A study of Rattus norvegicus with 8 samples.

How the data were processed

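Total RNA from the paraventricular nucleus of 4 male and 4 female rat pups was amplified and labelled with Cy3 or Cy5 and hybridised to 4 two-colour Agilent arrays, per the labels. Spots were quantified with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited values are on a log2 scale, as read from the values themselves: 2 raised to each value lies on an evenly spaced grid, so that each column is log2 of a whole-number signal divided by 1 constant per column. At least 99.986% of the values of each sample fell within 0.01 of a whole signal, and the constants were 1376 to 3963. What the constant stands for, whether background was removed and why some spots hold no value are not given in the sources used here. The medians of the deposited columns ran from -1.33 to -0.75. Control samples, other treatment groups and litters were not analysed here.

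The table listed 44254 features with numbers from 1 to 45220, of which 966 numbers had no line. A value was missing in all 8 samples for 1377 features and in some samples for 9780, of which 9493 lacked values in Cy5 samples alone. Features with a value in all 8 samples (33097) were kept, and the median over them was subtracted from each sample. The most frequent recovered signal was 260 to 308 in Cy3 and 80 to 90 in Cy5. Feature numbers were not paired with gene names, and the gene names of the reference tables could not be matched to them, so that 0 of 47357 genes were matched and each feature was tested on its own. The planned averaging of features of a gene, the planned gene lists (and the alternatives that concern them), and the planned check of the labels with sex-linked genes were therefore not run.

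The main test was limma 3.58.1 (lmFit and eBayes, moderated test, two-sided, R 4.3.3) with sex and dye as fixed terms and the array as a random block through duplicateCorrelation, whose estimate was 0.298. Benjamini-Hochberg adjustment was applied over 33097 features with a threshold of 0.05. The design assumed gene names, and the test used here is the planned one at the level of features. Differences are male minus female. The number of arrays, not sequencing depth, limits the precision: the median standard error was 0.16. In simulated data with the estimated spread and array correlation, the same comparison recovered 85 of 100 features changed by 2-fold and 99 of 100 changed by 4-fold. It also called 24 unchanged features, a larger share of its calls than the threshold of 0.05 allows. Features were drawn independently of each other, without effects of slide or position. The simulation changed 200 features at once, and the adjusted threshold is easier to pass when many features differ. The recovered shares therefore do not carry over to data in which few or none pass. The array correlation estimated in the simulated data was 0.233, below the 0.298 used to draw them. The simulated unchanged features had an unadjusted p under 0.05 in 5.86% of cases.

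The rule for the features to be named, fixed before the data were examined, took the 10 highest and 10 lowest differences among features past the adjusted threshold whose sexes were separated, and where fewer passed, the next by unadjusted p. It was reduced to 2 features in each direction because no names were at hand. Spread was the median over features of the within-sex SD after removing the dye difference, with an exact permutation test over 35 splits of the 8 samples. Exact means here that every split was counted. Most of these splits part the 2 samples of an array, which are not independent. For a simulated ratio of 1.5 the measure of spread gave 1.35, since the removed dye difference is shared by the sexes.

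Replicate numbers are shared by the sexes. Deviations from the group means of samples with the same number correlated at 0.586 to 0.694, because odd numbers are Cy3 and even numbers Cy5, and at -0.528 to -0.264 once the dye was removed. Subtracting the group and dye means makes such correlations negative on its own, so their sign is not read as a result. With no positive correlation left, the numbers were not taken to pair animals beyond the dye.

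Alternatives planned before the data were examined were the values as deposited, quantile normalization, no array block, arrays averaged, no dye term, the replicate number as a block, removal of the 8275 features with the lowest mean, features with at least 3 values in each sex, trend and robust variance, a 1.5-fold minimum, and leaving out each sample and each array. Chosen after seeing the data were subtraction of the local median of neighbouring features (6 layout rows and 3 columns on each side), subtraction of the most frequent signal as background with an offset of 50, and removal of 107 features in and around the 2 bright areas. Local bright features were those over 1.5 log2 above the same dye on the other arrays in both dyes, and neighbours were those within 4 layout rows and 2 columns. Features that vary alike, also chosen after seeing the data, were grouped by average linkage at a root mean square distance of at most 0.3 among features with an SD of at least 1 between samples of the same dye. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.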

Results

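Gene expression was measured in the hypothalamic paraventricular nucleus, a small group of neurons beside the third ventricle that holds the vasopressin, oxytocin and corticotropin-releasing hormone cells, of Sprague-Dawley rat pups at postnatal day 15. Their mothers had received 2 injections of betamethasone, a synthetic glucocorticoid, at 0.4 mg/kg each on gestation day 15. The pups then received N-methyl-D-aspartate, which triggers infantile spasms in this model, on postnatal days 12, 13 and 15, and PMX53, an antagonist of the complement C5a receptor C5ar1, on days 13, 14 and 15. The 8 samples were 4 males and 4 females, given as biological replicates, all with the same exposures. Each of the 4 two-colour Agilent arrays carried 2 samples of 1 sex, the odd-numbered replicate in Cy3 and the even-numbered replicate in Cy5. The number of arrays, 2 per sex, limits the precision.

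Values were present for 42609 to 42877 features in the Cy3 samples and for 34889 to 36579 features in the Cy5 samples, of 44254 features listed. All 8 samples had a value for 33097 features, which is 74.8% of those listed. Across these features, which are not independent replicates, samples of the same sex and dye correlated at a median of 0.986, samples of the same dye and the other sex at 0.983, and the 2 samples of an array, in different dyes, at 0.980. Feature numbers were not paired with gene names in the sources used here, so each feature was compared by its number, and no gene, pathway or cell type is named.

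The contrast that the labels allow was that of males and females exposed to the same prenatal steroid, spasm trigger and C5ar1 antagonist. Each sample's median had been subtracted, so a difference in the median level of signal could not show. The median absolute difference between the sexes was 0.17 on the log2 scale, about the median standard error of 0.16. Of the features, 95% differed by less than 0.56. A total of 157 features differed by at least 2-fold, 65 with the higher mean in males and 92 with the lower mean in males. Of these, 6 and 11 lay in local bright areas of the arrays of males 1 and 2 and of females 1 and 2. No feature passed limma's moderated test after Benjamini-Hochberg adjustment (0 of 33097, lowest adjusted p = 0.457). Features lacking a value in any sample were not tested. Among them, 356 had a value in both male Cy5 samples and in neither female Cy5 sample, and 298 the other way. These counts were 426 and 58 for males 1 and 2 with females 3 and 4 against the rest. For replicates 1 and 2 against 3 and 4 they were 164 and 220. Over all listed features, 0 were on in every male and off in every female, and 0 the other way. On was at least 3 times the most frequent signal of the sample, and off was at most 2 times it or no value. In Cy3 that signal was 260 to 308 and the median 582 to 925. The on level thus lay near or above the median, and dimmer features could not count as on. The other splits that keep arrays whole also gave 0 both ways, so these counts do not set the sex split apart. The sex labels were not checked with sex-linked genes, so the differences given here are between samples as labelled.

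At an unadjusted p under 0.05 the same limma test counted 3536 of 33097 features, where 5% would be 1654.8. Of the 3536, 745 were higher in males and 2791 were lower in males, so that 21.1% were higher in males. With quantile normalization in place of median centring the count was 2599 and 49.0% were higher in males, so the direction of the split depended on the scaling; with the values as deposited 18.7% were higher in males. In 1026 of 33097 features the 4 male values all lay on one side of the 4 female values, 408 above and 618 below. Samples without shared arrays and without a dye difference would give 2.86%, or 945.6 features, by chance. The values compared held both, so that share is not a reference for the 1026. The other splits that keep arrays whole gave 1241 such features for males 1 and 2 with females 3 and 4 and 427 for replicates 1 and 2 against replicates 3 and 4.

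Leaving out 1 sample moved the unadjusted count by over 1.5 times for male 2 (2298 features), female 2 (2204) and female 4 (2205), and ignoring the shared array gave 5915. Leaving out the array of males 3 and 4, of females 1 and 2 or of females 3 and 4 gave 4, 17 and 22 features past the adjusted threshold, and no feature was shared by any pair of these sets. In each of these fits a sex rested on a single array, so that array and sex could not be told apart for it. The estimated array correlation was 0.042, 0.16 and 0.21 in them, against 0.298 in the main fit.

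The 2 features with the lowest unadjusted p in each direction, among those with separated values, are given as values, since none passed the adjusted threshold. Feature 40117 had a log2 signal, relative to the sample median, of 1.83 ± 0.22 in males and 0.75 ± 0.33 in females (SD, n = 4 each), a difference of 1.08 ± 0.17 (SE) or 2.11-fold, with a 95% interval of 1.62-fold to 2.74-fold (limma, unadjusted p = 9.95e-05, adjusted p = 0.457). Feature 25438 had 0.42 ± 0.20 in males and -0.68 ± 0.33 in females, a difference of 1.09 ± 0.17 or 2.13-fold (limma, unadjusted p = 0.000119, adjusted p = 0.457). Feature 9348 had 2.59 ± 0.14 in males and 3.38 ± 0.18 in females, a difference of -0.79 ± 0.14, so that females were 1.72-fold higher (limma, unadjusted p = 0.000267, adjusted p = 0.457). Feature 23758 had 0.01 ± 0.31 in males and 0.86 ± 0.05 in females, a difference of -0.85 ± 0.16, so that females were 1.80-fold higher (limma, unadjusted p = 0.000353, adjusted p = 0.457). Each of the 4 features had all 4 values of one sex above all 4 values of the other. They were picked for low p and separated values, and neither the differences nor the interval allow for that choice. With the 2 samples of each array averaged, their unadjusted p in limma was 0.00084 to 0.0021 (adjusted p = 0.463).

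**Figure D1:**
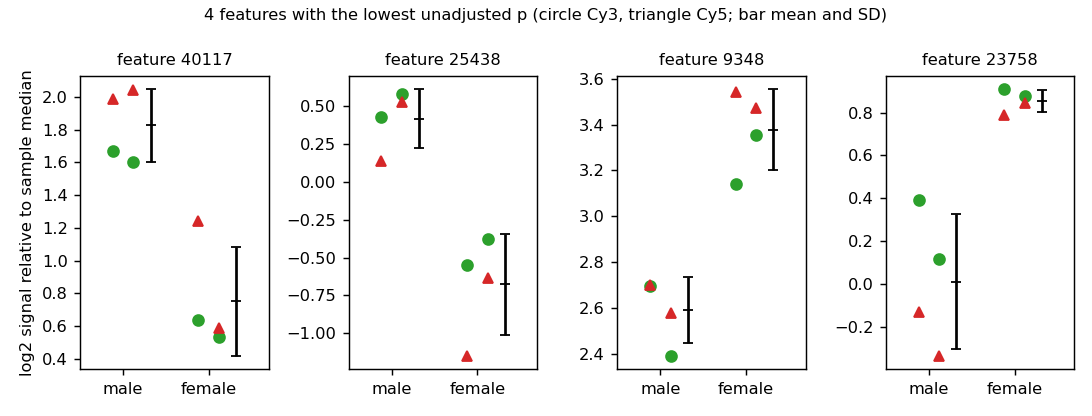
Log2 signal relative to the sample median of features 40117, 25438, 9348 and 23758 in each of the 8 samples, with circles for Cy3, triangles for Cy5, the 2 arrays of a sex side by side, and bars for the mean and SD of 4 samples. Male values lie above female values for features 40117 and 25438 and below them for features 9348 and 23758.

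The differences between the sexes were concentrated at low signal. Among the 8275 features with the lowest mean signal, 1822 (22.0%) had an unadjusted p under 0.05, 95.3% of them lower in males, and the median difference was -0.23. The shares were 7.53%, 6.02% and 7.17% in the next 3 groups of 8274 features by rising signal, and 81.3% of those in the brightest group were lower in males. Without the 8275 dimmest features, 1731 of 24822 features (6.97%) had an unadjusted p under 0.05 and 0 passed the adjusted threshold in limma, with 37.8% higher in males. The most frequent signal of a sample, a measure of its floor, was lower relative to the sample median in males than in females in both dyes. It averaged -2.34 in males and -2.06 in females in Cy3, and -4.81 and -3.89 in Cy5, on the log2 scale. As a recovered signal this floor was 308 and 300 in males and 260 and 294 in females in Cy3. In Cy5 it was 80 in males and 90 in females. The median recovered signal was higher in males, at 925 and 810 against 582 and 743 in Cy3. In Cy5 the median was 2120 and 1610 in males and 1124 and 1066 in females.

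**Figure D2:**
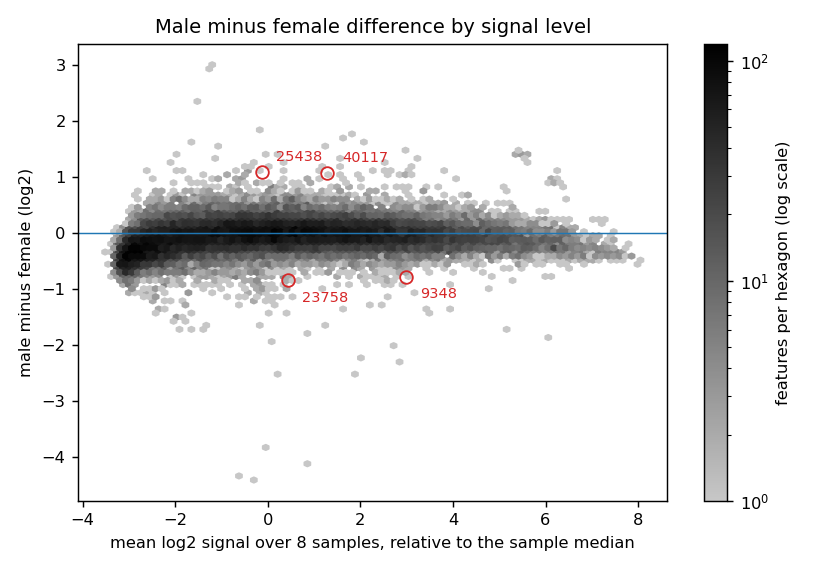
Male minus female log2 difference of 33097 features against their mean log2 signal over the 8 samples, with shading for the number of features on a log scale and circles for the 4 numbered features. The cloud bends below 0 at its low end, where the median difference of the 8275 dimmest features was -0.23.

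All arrays of 1 sex lay on 1 slide, so 0 slides held both sexes, and slide and sex cannot be told apart. The arrays also differed by position. Deviations of each array from the mean of the 4 arrays correlated between features 85 numbers apart, the length of a layout row as inferred from the values, at 0.160 and 0.120 for the arrays of males and 0.395 and 0.191 for those of females. After shuffling the features the highest of 100 values was 0.016 or less for each array. The male minus female difference itself had a correlation of 0.188 at this distance.

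**Figure D3:**
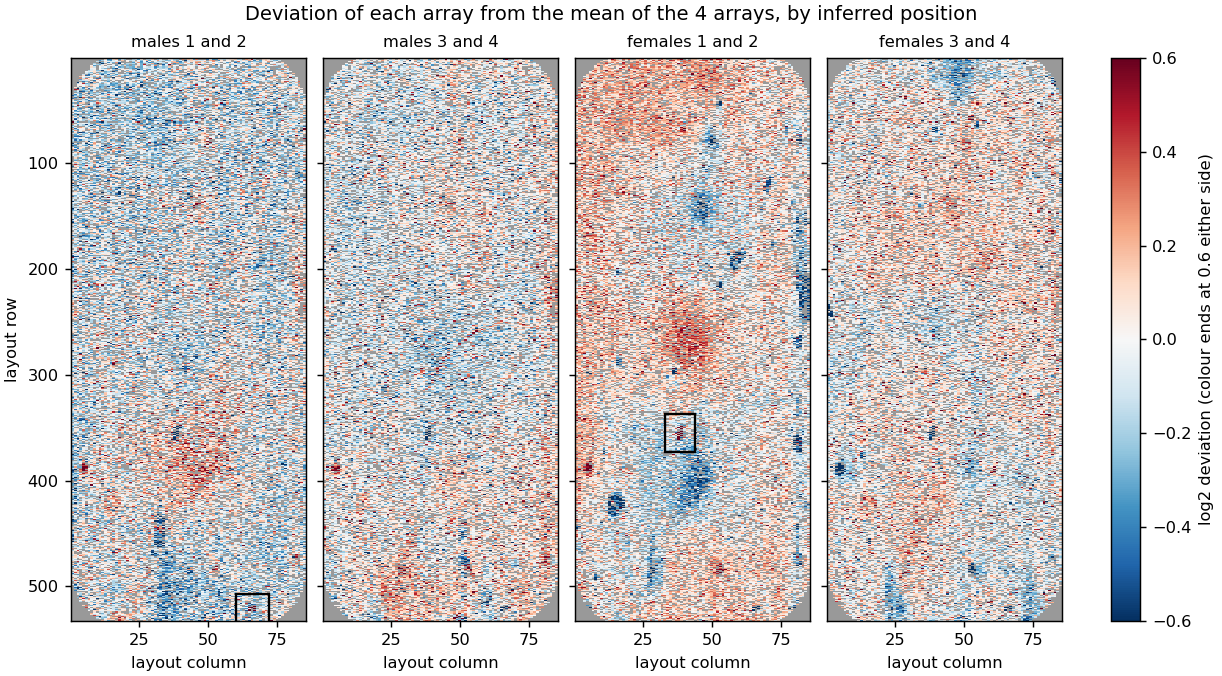
Log2 deviation of each array, averaged over its 2 samples, from the mean of the 4 arrays, placed by layout row and column as inferred from feature numbers, with grey for features not tested and black frames around the local bright areas. The array of females 1 and 2 has the most extended light and dark patches, with a correlation of 0.395 between neighbouring rows.

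The variability of expression between animals was compared because the series concerns genomic fabrics, an approach that uses it. After removal of the dye difference, the median SD over 33097 features was 0.172 in males and 0.167 in females on the log2 scale, a ratio of 1.03, and the SD was higher in males for 53.5% of features. The difference of 0.0051 was as large in 22 of 35 splits of the 8 samples (exact two-sided permutation test, p = 0.629, smallest possible 0.0286). Over the 3 splits that kept arrays whole, 2 gave as large a difference (exact p = 0.667, smallest possible 0.333), so this design cannot reach the threshold. With quantile normalization the difference was -0.0034, and leaving out 1 sample gave -0.0057 to 0.012, so that the sign was not fixed. The difference was 0.0200 with the dye left in (exact permutation p = 0.2) and 0.0149 between array means. After subtraction of local medians, chosen after seeing the data, it was 0.0192 (2 of 35 splits, exact permutation p = 0.0571). Most of the 35 splits part the 2 samples of an array, which are not independent. Splits that keep arrays whole were not counted for these values, so the p-values over 35 splits decide nothing.

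A small set of features varied widely between samples of the same dye, a selection made after the values were seen and one that includes the difference between the sexes. Outside the local bright areas, 163 features had an SD of at least 1 on the log2 scale between samples of the same dye. Of these, 54 fell into 7 groups of at least 5 features whose 8 values nearly coincided, with an SD between the features of a group of 0.22 or less in each sample. Group 1, of 10 features in layout rows 98 to 495, ranged among Cy3 samples from 3.57 in male 1 to 6.77 in male 3 and among Cy5 samples from 1.68 in female 4 to 7.37 in male 2. Group 3, of 9 features, ranged from 4.00 in male 1 to 7.00 in male 3 in Cy3 and from 5.24 in female 4 to 8.30 in male 4 in Cy5. Group 2, of 10 features, was at -3.47 in male 2 and at -0.12 to 1.17 in the other Cy5 samples, with a range of 1.47 in Cy3. Groups 4, 5 and 7 were highest among Cy5 samples in female 4, at 0.33, 1.60 and -0.12, where group 1 was lowest. Their ranges were 4.06, 3.69 and 3.50 in Cy5 and 0.85, 1.87 and 0.93 in Cy3. In Cy3, group 4 lay at -1.91 to -1.06 and group 7 at -1.99 to -1.06. The most frequent signal of the Cy3 samples was close by, at -2.44 to -1.95. Their small ranges in Cy3 therefore need not mean that these samples varied little. These 54 features include 33 of the 157 that were at least 2-fold apart between the sexes, 5 of the 54 had an unadjusted p under 0.05 in limma, and the lowest unadjusted p among them was 0.026.

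**Figure D4:**
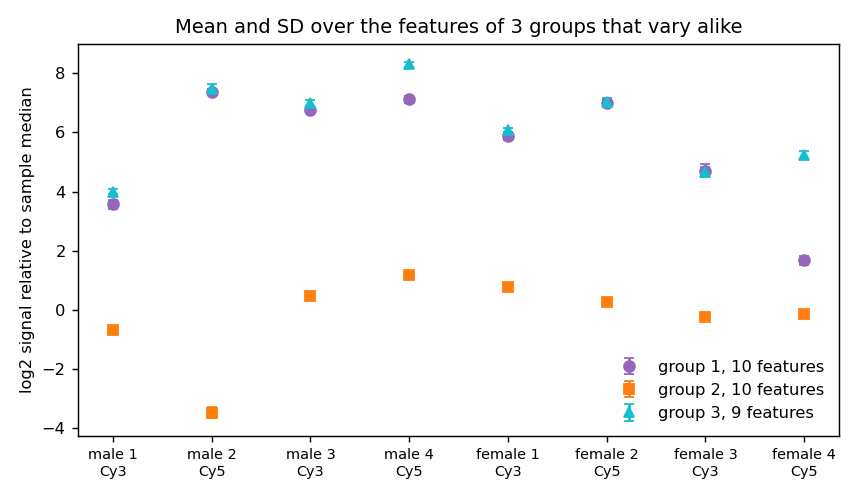
Log2 signal relative to the sample median of the 3 groups with the most features that vary alike, in each of the 8 samples, with points for the mean and bars for the SD over the 9 or 10 features of a group. Group 1 spans 3.57 to 6.77 in Cy3 and 1.68 to 7.37 in Cy5, while group 2 is at -3.47 in male 2.

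With median centring the dyes differed in more features than the sexes. At an adjusted p under 0.05, limma with Benjamini-Hochberg adjustment called 17248 of 33097 features between Cy5 and Cy3, 5710 higher and 11538 lower in Cy5, with a median absolute difference of 0.35. With the values as deposited 16291 features passed, 3359 higher and 12932 lower in Cy5. With quantile normalization 0 passed in limma (6757 at an unadjusted p under 0.05, against 19207 with median centring) and the median absolute difference between dyes was 0.14. The dye difference differed between males and females in 28 features past the adjusted threshold and in 6913 at an unadjusted p under 0.05 (limma, lowest adjusted p = 0.0396). Odd and even replicates were balanced over the sexes.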

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

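The tests of explanations in this part, with the splits counted, were chosen after the results were seen.

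Female 4 stood apart from the other females in the root mean square of its residuals after sex and dye were removed, 0.239 against 0.209 to 0.213. Feature 40117 was at 1.24 in female 2 and at 0.53 to 0.64 in the other females. Of the features that vary alike, group 1 was at 3.57 in male 1 and at 6.77 to 7.37 in the other males, over both dyes, and group 6 at 1.40 and at 4.15 to 4.33. Chance gives such a gap in about 1 of 20 sets of 4 values drawn alike, and 4 of 36 tested had one. The sets tested mix both dyes, and many hold features chosen for their spread or separation. The rate of 1 in 20 is therefore not a reference for them. The dye difference differed between males and females in 28 features, and the 3 splits that keep arrays whole, of which 1 gave as many and the highest other gave 0, are too few for a share under 0.05. For the dyes themselves the real split gave 17248 features and the highest other 0, and the 8 splits that part the 2 samples of every array, of which 1 gave as many, are again too few.

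The first pattern weighed is the 3536 features with an unadjusted p under 0.05 between the sexes. The 3 splits that keep arrays whole, of which 1 gave as many and the highest other gave 2874, are too few for a share under 0.05. Of 34 splits of the samples, 2 gave as many, the sex split among them, and the highest other gave 4912. Most of these part the samples of an array, so they are not a like measure. Replicates 1 and 2 against 3 and 4 gave 2 features past the adjusted threshold in limma, where the sex split gave 0. Subtracting the local median of neighbours left 3979 features (12.0%) with the array correlation estimated again and 3325 with it kept. Leaving out 1 sample gave 1828 to 5090, where 5% gives 1654.8. The split of males 1 and 2 with females 3 and 4, which crosses the sexes, gave 2686 after this subtraction, with the correlation kept. Simulated unchanged features gave 5.86%. A count above 5% thus also arises without a contrast of the sexes, and cannot decide whether the trend in position is the whole cause. Subtracting the most frequent signal left 2957 (8.93%), 3127 with the array correlation kept, and 2154 to 4020 leaving out 1 sample. The crossing split gave 3060 after this subtraction, so background as the whole cause cannot be decided in this way either. Subtraction of the most frequent signal brought the median difference of the 8275 dimmest features from -0.23 to -0.064. A candidate explanation for that part is the weight of the floor against the sample median. The floor itself differed less between the slides than the median signal did. The median difference of the 8274 brightest features moved from -0.06 to -0.09, away from 0. Slide and sex cannot be told apart because 0 slides held both, and the sex of the animals remains untested.

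The second pattern is a group of features far brighter on 1 array in both dyes. On the array of females 1 and 2, 11 of 13 such features had a close neighbour among them, where the highest of 1000 random draws was 4, which argues against RNA of these 2 animals as the source. They lie in layout rows 349 to 361 and columns 38 to 39, with an excess of up to 8.37 in Cy3 and 9.26 in Cy5 on the log2 scale. On the array of males 1 and 2, 6 of 7 had a neighbour and the highest random draw was 2. A local mark on each array is a candidate explanation.

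The third pattern is the 7 groups of features that vary alike between samples. Within the groups 0 of 54 features had a close neighbour of their own group, which argues against local marks on the arrays. Between males 1 and 3, both in Cy3, 3 groups were higher and 4 lower in male 1, which argues against the amount of spiked-in control RNA as the source of all groups. Each group may be a probe printed several times or transcripts that move together, and the tissue taken or the state of the animals stays open as a source, since 0 groups have a gene name here.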

How the results depend on the processing

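The subtraction of local medians, the subtraction of background and the removal of bright areas were chosen after the data were seen. In limma the adjusted count was 0 under each alternative except leaving out an array, which gave 4 without males 3 and 4, 17 without females 1 and 2 and 22 without females 3 and 4, against 0 without males 1 and 2; of the 4, all lay in the bright area, and of the 22, 11. The cause was not tested for the rest, and each fit without an array left a sex with a single array. A 1.5-fold minimum also gave 0. The unadjusted count of 3536 was 5915 without the array block, 1731 without the 8275 dimmest features (fewer features tested), 5896 without the array of males 3 and 4, and 2204 to 4733 leaving out 1 sample, lowest without female 2 (2204), female 4 (2205) and male 2 (2298). The share higher in males was 21.1%, but 49.0% with quantile normalization, 40.9% without the dye term, 37.8% without the dimmest features and 37.6% after background subtraction. With the replicate block the unadjusted count was 4241 without the array block and 2829 with it, and the adjusted count 0 in both. The replicate number sets the dye, so the dye count has no such block. The dye count of 17248 was 0 with quantile normalization (6757 unadjusted) and 14944 to 16150 leaving out 1 sample. The difference in spread of 0.0051 was -0.0034 with quantile normalization and -0.0057 to 0.012 leaving out 1 sample, negative without male 2, male 4 or female 1; the cause was not tested. It was 0.0200 with the dye left in (exact permutation p = 0.2) and 0.0149 between array means. Its replicate block has no value, because 2 samples per number force equal SDs. Local correction gave 0.019 (exact permutation p = 0.0571, over splits that mostly part the 2 samples of an array). The 4 numbered features, chosen as separated, had an adjusted p of 0.0942 to 0.717 over the alternatives. Gene lists, the choice among features of a gene and sex-linked genes were not run, for want of names. Signal over background limits the dimmest features.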

Other observations

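The tests in this part were chosen after the results were seen.

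By the count of features at least 2-fold apart, though not by unadjusted p, the arrays differed most in a direction that crossed the sexes. Between the arrays of males 1 and 2 with females 3 and 4 and the remaining arrays, 272 features differed by at least 2-fold, against 157 between the sexes and 89 between replicates 1 and 2 and replicates 3 and 4. The features with an unadjusted p under 0.05 in limma numbered 2874, 3536 and 649 for these splits. Of the 272, 45 belonged to the 7 groups of features that vary alike and 17 lay in the bright areas. A close neighbour among them was found for 87 of the 272, against a median of 62 and a highest value of 90 in 1000 random draws, of which 3 gave 87 or more. The 87 include the 17 of the bright areas, which had been chosen for having close neighbours.

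Features at least 2-fold apart between the sexes varied within each sex. Among the 65 with the higher mean in males, the median deviation from the mean of the same dye was -1.44 in female 4 and -0.66 in female 3, but 0.28 in female 1, and it was 0.03 in male 1 against 0.82 to 0.83 in the other males. Among the 92 with the lower mean in males it was 1.37 in female 4 and 0.00 in female 1.

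Within the array of females 1 and 2, 7 of 17 features darker in both dyes had a close neighbour (highest random draw 4), and on the array of females 3 and 4, 17 of 24 had one (highest random draw 6). No close neighbours were found among the 8 darker features of the array of males 1 and 2 or the 27 of the array of males 3 and 4.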
